A study of Methylobacterium nodulans ORS 2060 with 4 samples.

How the data were processed

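RNA sequencing was done on 4 libraries of wild-type Methylobacterium nodulans ORS 2060, a root-nodule bacterium that grows on methanol. Per the labels' protocols, the cells grew in MP minimal medium with 50 mM methanol, without citrate, with either 2 uM lanthanum chloride or 2 uM lanthanum oxide, and the labels describe the growth as phosphate-limited. RNA was taken with a Qiagen RNeasy kit and sequenced as paired reads on a NovaSeq X Plus. The sample titles give the strain number under the species name M. extorquens, whereas the organism field and the locus tags of the table give M. nodulans. The titles also write the oxide as La2Ox3, whereas the growth protocol writes La2O3 and the sample descriptions and the series' design text say oxide. Groups were taken from the titles, with 2 libraries of each group, and each count column was assigned by the library name in the sample's description. Nothing in the labels says whether the 2 libraries of a group came from separate cultures, so p-values measure the spread between these libraries, which may be technical.

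The authors deposited a single table of 8564 genes with a whole-number count per gene and library, without normalization. The submitters' processing notes name HISAT2, StringTie 2.1.5 and DESeq 1.20.0 without saying which step each served. The genome build, the annotation and the strandedness of the counting are not given in the sources used here. Counts of overlapping, antisense or near-identical genes are therefore uncertain. The deposited mean columns hold the plain mean signal of the 2 counts of a group, unscaled for depth, and were not used. The deposited log2 fold changes equal those of DESeq2 run here on the same counts, oxide over chloride, to within 5e-10. The deposited p-values and q-values did not follow the counts of their rows, as the report describes, and no call here rests on them.

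The table names genes by locus tag alone and does not pair the tags with gene names or positions, and no genome or annotation was used here. The 30 gene lists fixed before the data were examined, which covered methanol oxidation, lanthanide uptake, phosphate starvation and other functions, matched 0 genes and were not tested, and neither were calls by replicon. Genes are described by locus tag order, and at most 2 tags per direction are printed. The rule for naming genes was fixed before the data were examined. Its parts for gene list members, members of the longest runs and the most abundant genes were not followed here. The part used took the genes with the largest fold past the threshold whose libraries did not overlap between groups. It required a mean of at least 10 CPM (counts scaled to the library's TMM-adjusted total). With none past the threshold in a direction, it took those with the smallest unadjusted p. It gave 9 genes that rose, of which the 2 with the largest fold are named, and for lower levels the gene with the smallest p. The second named gene with lower counts, MNOD_RS39655, was chosen after its values were seen.

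Counts were tested with edgeR 4.0.16 in R 4.3.3 by its quasi-likelihood F-test (glmQLFit with default settings) on TMM-scaled libraries, with the group as the only term and Benjamini-Hochberg adjustment at a threshold of 0.05, two-sided. The default filterByExpr kept 8538 genes and removed 26. Standard errors of log2 fold changes were derived from the F statistics. Every row carried a locus tag, so none was left out as unassigned reads. Alternatives were DESeq2 1.42.0, limma-voom (limma 3.58.1), RLE, upper quartile or no scaling factors, no filter or a mean of at least 5 CPM, the replicate number as a block, each library left out in turn, a threshold of 0.01 and a minimum absolute log2 fold of 1. DESeq2 adjusted over all genes, robust empirical Bayes, the bias-adjusted quasi-likelihood method and tags numbered below 42000 were added after the data had been seen. The labels number the libraries 1 and 2 in both groups without saying that a number marks a shared culture or day.

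The edgeR procedure was tested on 5 sets of simulated counts for the 8538 genes, with the means, depths and dispersions of these libraries. In each, 100 genes were changed 2-fold and 100 were changed 4-fold. On average 50.4% of the 2-fold and 96.2% of the 4-fold changes were recovered, with 13.8 false calls per set. DESeq2 recovered 62.6% and 95.0%, with 22.8 false calls. These shares apply to the simulated counts and need not hold for the real libraries. In the real libraries, the SD over genes of the log2 ratio was 0.488 for the chloride pair and 0.224 for the oxide pair. Whether the recovery holds with such unequal spread was not tested. Neighbouring genes were taken as adjacent in the number order of the locus tags in the table, passing over missing numbers, since neither strand nor position is given. The share of called genes beside another call of the same direction was compared with 10000 random draws of as many tested genes.

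Library totals ran from 59819596 to 78891531 counts and the median gene had 928 to 1304 counts per library, so counting error was small beside the spread between libraries for most genes. The common biological coefficient of variation was 19.3%. With 2 libraries against 2, a permutation test of a single value cannot reach a two-sided p under 0.333, so single values are given with their spread and no such test.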

Results

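The 4 libraries were compared to ask how gene expression of M. nodulans in phosphate-limited methanol medium differs between lanthanum supplied as the chloride, a soluble salt, and as the oxide, a poorly soluble solid. Lanthanum is a lanthanide, a group of metals that serve as cofactors of the XoxF-type methanol dehydrogenases of methylotrophic bacteria. Both compounds were given at 2 uM. An oxide formula unit carries a pair of lanthanum atoms and a chloride unit a single one, so equal compound concentrations are not equal amounts of lanthanum. The chloride libraries held 78891531 and 67396077 counts and the oxide libraries 59819596 and 72912679. The most abundant gene of each library took 2.37% to 5.03% of its counts.

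The oxide libraries resembled each other more than the chloride libraries did. Among 5087 genes with a mean of at least 10 CPM, 17 differed at least 2-fold between the oxide libraries and 227 between the chloride libraries. Chloride replicate 1 differed at least 2-fold from the oxide libraries in 441 and 384 genes. For chloride replicate 2 these counts were 103 and 73. The first principal component held 68.6% of the variance of log2 CPM and set chloride replicate 1, at -38.98, apart from chloride replicate 2 at 1.52 and the oxide libraries at 21.69 and 15.76. The second component held 17.5% and set the oxide libraries apart from each other, at 17.45 and -14.49. No pair of libraries agreed within sampling noise, with a chi-square per degree of freedom of 479 for the chloride and 226 for the oxide pair. For chloride replicate 2 with the oxide libraries it was 210 and 172. By this measure chloride replicate 2 was no farther from each oxide library than they were from each other. Each library was counted as 1 sample, but this check covers counting error only and does not tell separate cultures from separate preparations of the same culture.

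**Figure D1:**
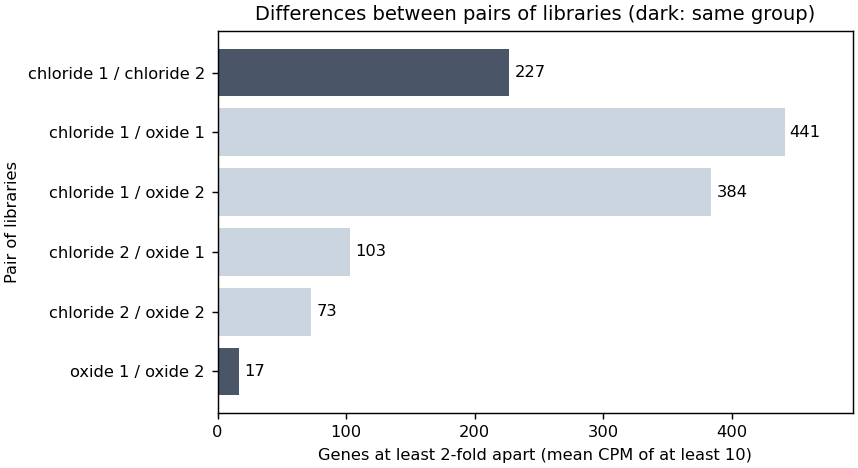
Number of genes (x axis) at least 2-fold apart between each pair of libraries (y axis), among 5087 genes with a mean of at least 10 CPM. Dark bars are pairs within a group and light bars pairs across groups. The chloride pair differed in 227 genes and the oxide pair in 17.

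Growth with lanthanum oxide was accompanied by higher transcript levels of a small set of genes, most of them side by side in locus tag order. At an adjusted p under 0.05 (edgeR quasi-likelihood test), 9 genes were higher in oxide than in chloride and 0 were lower, with 2.65-fold to 4.19-fold higher levels. Of these 9 genes, 7 formed a run that begins at MNOD_RS32805 and is adjacent among the locus tags in the table. A tag number at the usual step of 5 is missing within the run. Together the 7 genes of the run made up 932 CPM ± 109 (SD, n = 2) with chloride and 3163 CPM ± 284 (SD, n = 2) with oxide, a 3.39-fold higher level. The functions of these genes are not stated, because the table does not pair tags with names.

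Within the run, the first gene, MNOD_RS32805, rose from 221 CPM ± 41.3 (SD, n = 2) with chloride to 815 CPM ± 36.4 (SD, n = 2) with oxide. Its log2 fold change was 1.88 with a standard error of 0.20 and an edgeR adjusted p of 0.0257. The log2 fold changes of the 7 genes lay between 1.41 and 1.88, with a median of 1.62 and edgeR adjusted p of 0.0257 to 0.0403. Their levels differed widely, from 16.3 to 310.2 CPM with chloride and from 43.3 to 1033 CPM with oxide. In each of the 7 genes the lower oxide library was at least 2.50 times the higher chloride library. Beyond the end of the run, the next tag had a log2 fold change of 1.16 ± 0.21 (SE) with an edgeR adjusted p of 0.246, and the tag after it also missed the threshold (edgeR adjusted p = 0.237). The tag just before the run was at 0.13 ± 0.17 (SE), with an edgeR adjusted p of 0.791.

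The other 2 called genes had tags outside the run. MNOD_RS24260 had the largest fold of the 9 genes, from 21.7 CPM ± 5.40 (SD, n = 2) with chloride to 90.9 CPM ± 7.86 (SD, n = 2) with oxide, a log2 fold change of 2.07 with a standard error of 0.22 and an edgeR adjusted p of 0.0257. The last called gene has a tag far from both. It rose from 228 CPM ± 26.2 (SD, n = 2) to 749 CPM ± 51.0 (SD, n = 2), a log2 fold change of 1.72 with a standard error of 0.18 and the same adjusted p by edgeR. Its level and fold lie within the range of the run, but the table does not give its position.

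**Figure D2:**
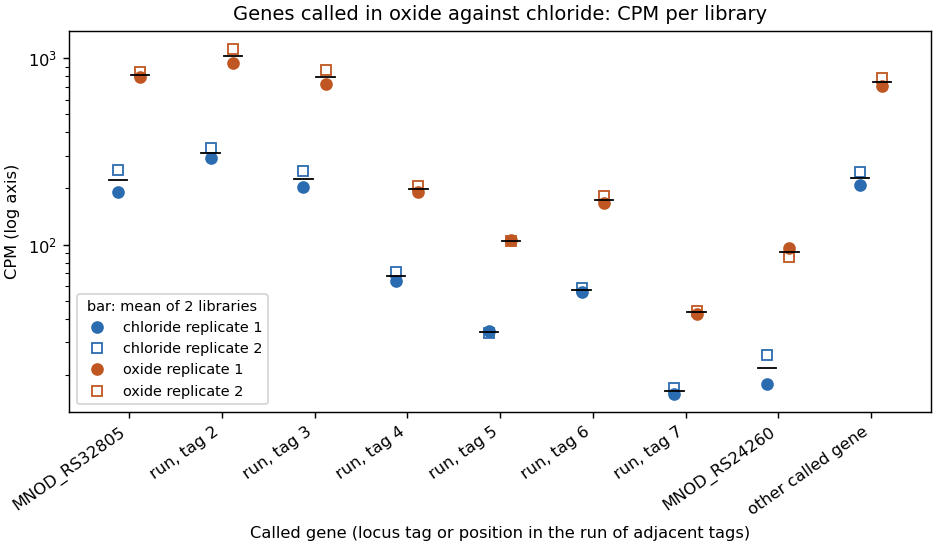
CPM on a log axis (y) of each library for the 9 genes called in oxide against chloride (x), with the 7 genes of the run in tag order and the others to the right. Filled circles are replicate 1, open squares replicate 2, and black bars the mean of 2 libraries. In each gene both oxide libraries lie above both chloride libraries, by at least 2.50 times.

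No gene was called lower with oxide by edgeR, although 450 genes were lower and 456 higher at an unadjusted p under 0.05, where chance would pass 427 in all. This balance moved with the processing, to 374 higher and 606 lower with upper quartile scaling and to 489 higher and 354 lower with limma-voom. The gene with lower counts and the smallest p, MNOD_RS28100, had 433 CPM ± 222 (SD, n = 2) with chloride and 116 CPM ± 30.1 (SD, n = 2) with oxide. Its log2 fold change was -1.90 with a standard error of 0.36 and an edgeR adjusted p of 0.260. DESeq2 called it at an adjusted p of 2.65e-05. In edgeR its log2 fold change was -1.25 without chloride replicate 1 (adjusted p = 0.0412) and -2.36 without chloride replicate 2 (adjusted p = 0.000257). The lowest fold among genes with a mean of at least 10 CPM was that of MNOD_RS39655, with a log2 fold change of -2.73, a standard error of 0.71 and an edgeR adjusted p of 0.348. It closes a stretch of 12 adjacent tags with log2 fold changes of -2.73 to -1.66. None of the 12 was called by edgeR or DESeq2 from all 4 libraries with the group as the only term. The stretch holds only genes with a mean of at least 10 CPM. With the replicate number as a block, edgeR called a longer run of 13 adjacent tags with the same end, of which DESeq2 called 1. All 12 passed in edgeR without chloride replicate 2 and 0 passed without chloride replicate 1, where the log2 fold change of MNOD_RS39655 was -1.02 (edgeR adjusted p = 0.213). The stretch made up 3.28% of all counts in chloride replicate 1 and 0.656% in chloride replicate 2. In the oxide libraries its share was 0.399% and 0.256%. In CPM, chloride replicate 1 was thus 5.04 times chloride replicate 2, and chloride replicate 2 was 2.00 times the oxide mean.

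**Figure D3:**
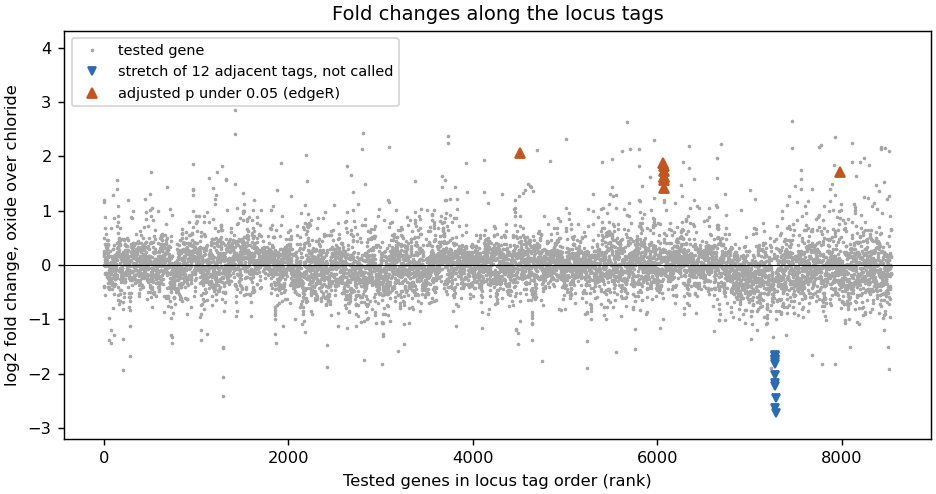
Log2 fold change of oxide over chloride (y) for the 8538 tested genes in locus tag order (x). Upward triangles are the 9 genes past an edgeR adjusted p of 0.05, of which 7 stack in a single run. Downward triangles are the stretch of 12 adjacent tags at -2.73 to -1.66, which was not called from all 4 libraries with the group as the only term.

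Called genes lay beside each other far more often than random genes. Of the 9 called genes, 7 (77.8%) had a called neighbour of the same direction, against a mean of 0.202% and a maximum of 22.2% in 10000 random draws (permutation p = 0.0001, the smallest they can give). With the DESeq2 calls the share was 49 of 161 genes (30.4%), against a mean of 2.25% in random draws (permutation p = 0.0001). The draws treat genes as independent, whereas fold changes of adjacent tags correlated at 0.276 even across genes called by neither tool. A low p is therefore likely for any calls that include a group of co-moving neighbours, and it says nothing about the compounds.

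The number of calls depended on the tool and on single libraries. DESeq2 called 161 genes, of which 119 were higher and 42 lower with oxide, and these held all 9 edgeR genes. Without chloride replicate 1, which stood apart, edgeR called 54 genes (45 higher, 9 lower) with all 9 among them, whereas without chloride replicate 2 it called 1602 (759 higher, 843 lower). Without oxide replicate 1 it called 0, with 397 genes at an unadjusted p under 0.05, and without oxide replicate 2 it called 10, of which 1 was among the 9. The 7 genes of the run were all past the threshold without either chloride library, and none was without either oxide library. Each of these tests takes the spread from the group that keeps both libraries, and the lone library is assumed to vary like it. That spread is smaller when a chloride library is left out, since the SD over genes of the log2 ratio was 0.224 for the oxide pair and 0.488 for the chloride pair.

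The authors' deposited table gives its own p-value and q-value for each row, and 136 rows have a q under 0.05. As placed, these values did not follow the counts beside them. The Spearman correlation over genes between the deposited p and the DESeq2 p recomputed from the counts was 0.024, and the 136 rows had a median absolute log2 fold change of 0.21, against 0.21 for all rows. In the authors' deposited table, MNOD_RS32805 carries a q of 0.632 and MNOD_RS24260 a q of 0.959, and 0 of the 9 genes called here by edgeR carry a q under 0.05. When the p-values were read down the rows sorted by falling fold change and given to the genes in locus tag order, 100% of genes lay within 1% of the recomputed DESeq2 p. In that order the 136 calls of the deposited table held all 9 genes, with 105 higher and 31 lower with oxide.

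**Figure D4:**
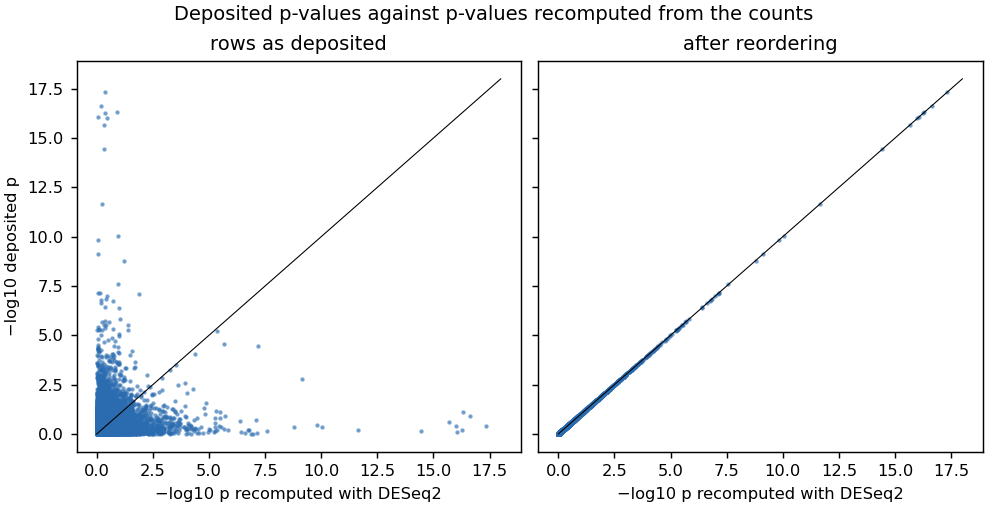
Deposited p-values (y, as −log10) against p-values recomputed from the counts with DESeq2 (x, as −log10), one point per gene, with the rows as deposited (left) and after reordering (right). The line marks equal values. The rank correlation is 0.024 on the left, and on the right 100% of genes lie within 1% of the line's value.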

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

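DESeq2 adjusted over all genes, robust empirical Bayes, the bias-adjusted method, tags below 42000 and the stretch that ends at MNOD_RS39655 were chosen after the data had been seen. The 9 calls were the same 9 genes with limma-voom, with RLE, upper quartile or no scaling factors, without the low count filter, with a minimum absolute log2 fold of 1 and with the bias-adjusted method. A mean of at least 5 CPM left 8 of them, as 1 gene of the run lost its call, and robust empirical Bayes called 11. DESeq2 called 161 genes, and 136 when adjusted over all genes. A threshold of 0.01 left 0 calls by edgeR, since the smallest adjusted p was 0.0257. Leaving out 1 library gave from 0 calls (without oxide replicate 1) to 1602 (without chloride replicate 2). Same-numbered libraries did not deviate together (correlation of deviations -0.084), but with 2 libraries per group this cannot exclude a shared culture or day. With the replicate number as a replicate block, edgeR called 157 genes (120 higher, 37 lower). That fit called all 12 genes of the stretch that ends at MNOD_RS39655, as did edgeR without chloride replicate 2, and the other 15 alternatives called 0 of them. The causes of these differences in count were not tested. Not all 17 alternatives are separate checks of a fold. The threshold of 0.01, the minimum log2 fold and robust empirical Bayes kept the main folds. DESeq2 adjusted over all genes kept the DESeq2 folds. The minimum of 1 could not remove a call, since the lowest called log2 fold was 1.41. In 13 of 17 alternatives all 7 genes of the run were called, and in 3 none was. The folds of the 4 named genes kept their direction in all 17 alternatives: MNOD_RS24260 lost its call in 2 and MNOD_RS32805 in 3, with log2 folds of 1.83 to 2.34 and 1.70 to 2.08. MNOD_RS28100 gained a call in 5 and MNOD_RS39655 in 2, with log2 folds of -2.36 to -1.25 and -3.49 to -1.02. The share of called genes with a called neighbour was 77.8% in the main test, 30.4% with DESeq2 and 87.5% for tags below 42000, each with a permutation p of 0.0001. The last share is 7 of 8 main calls, so it holds the same run and is not a separate check. Gene list tests, calls by replicon and the comparison of strands were not run, because the table gives no names, replicons or strands. Low counts removed 26 of 8564 genes from the test. On simulated counts with 2 libraries per group edgeR recovered 50.4% of 2-fold and 96.2% of 4-fold changes. These shares need not hold for the real libraries, as recovery with a wider spread in the chloride group was not tested.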

Other observations

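The tests of the deposited p-values and of neighbouring fold changes were chosen after the patterns had been seen, as was the split of the tags at 42000. Besides the run that begins at MNOD_RS32805, which DESeq2 extended to 9 adjacent tags, DESeq2 called a second run of 6 adjacent tags higher with oxide. Its summed level was 183 CPM ± 44.5 (SD, n = 2) with chloride and 513 CPM ± 45.6 (SD, n = 2) with oxide, 2.79-fold higher. None of the 6 passed in edgeR (lowest adjusted p = 0.105). The longest run that DESeq2 called lower held 5 adjacent tags, at 782 CPM ± 234 (SD, n = 2) with chloride and 383 CPM ± 17.0 (SD, n = 2) with oxide, with a lowest edgeR adjusted p of 0.275. In all, 122 genes with a mean of at least 10 CPM had log2 fold changes of 1 or more and 68 of -1 or less, and 9 of the former and 0 of the latter were called by edgeR.

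The deposited p-values and q-values belong to other genes than those of their rows. A candidate explanation is that the p and q columns stayed in locus tag order while the other columns were sorted by falling fold change and later returned to near tag order. Undoing such a sort raised the Spearman correlation with the recomputed DESeq2 p from 0.024 to 1.00. Another test or model behind the p-values is argued against, since 100% of genes then lie within 1% of the DESeq2 p. The counts and fold changes are not affected, and 6 genes have a q under 0.05 both as deposited and after reordering, where chance gives 2.16.

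Chloride replicate 1 stood apart from the other libraries. The wider chloride spread did not depend on depth or on the 20 most abundant genes. The SD over genes of the log2 ratio of the chloride libraries was 2.18 times that of the oxide libraries. It was 2.18 times after thinning all libraries to the same total and 2.14 times without the 20 most abundant genes. The cut of 10 CPM was applied anew each time, so these ratios cover 5087, 5090 and 5511 genes in turn. An SD over genes does not register a shift common to all genes, so an effect of that kind was not tested. The genes that separate the chloride libraries tend to separate oxide from chloride replicate 2 in the same direction. Across 5087 genes, which are not independent replicates, the Pearson r was 0.365 and the Spearman correlation was lower, at 0.2365. The shared library pulls both values below 0. Chloride replicate 2 may thus lie between chloride replicate 1 and the oxide libraries in some state such as growth stage or available lanthanum. Fold changes also drifted along the locus tags, and the range of medians over bins of about 500 genes was 0.350 (log2) against chloride replicate 1 but 0.082 against chloride replicate 2, a ratio of 0.234, and the bin medians against chloride replicate 2 correlated at 0.762 over 15 bins with those of chloride replicate 2 against 1, but the oxide libraries also drifted from each other (0.122), so the drift was widest with chloride replicate 1 and not confined to it. Whether its culture differed or the response to the compounds is graded stays open, as the labels give no growth stage or batch.

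Called genes lay next to each other. Co-movement of neighbouring genes, as in operons, may account for this, since fold changes of adjacent tags correlated at 0.276 across genes called by neither tool, above the highest of 1000 shuffled orders (0.038). Across all tested genes, called ones included, the correlation was 0.318, with 0.365 for tags below 42000 and 0.040 for higher ones. The higher numbers may not follow gene order, but tags below and above 42000 were not matched for expression level. The mean oxide levels of the genes of the run differed up to 23.9-fold. This argues against all of them being near-identical copies of equal length that share reads. Partial copies were not excluded, as CPM is not scaled for gene length and no sequences were used. Sharing with genes outside the run was not tested. The run's response to the compound itself, which the design names, remains an untested biological explanation. Of the 3 ways to split the 4 libraries in pairs, the real one gave 9 calls and 1 split in all gave as many, with 0 as the highest other, and 3 splits are too few for a share under 0.05.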
